A study of Homo sapiens with 12 samples.

How the data were processed

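Gene expression was measured in SP and MP cells sorted by Hoechst dye staining from 4 ALCL cell lines in logarithmic growth, with 3 SP and 3 MP arrays of SUDHL-1 and 1 of each from DEL, Karpas299 and SUPM2. Per the labels' protocols, RNA was extracted on a column robot, amplified with a whole-transcript kit for picogram amounts (NuGEN Ovation Pico), labelled with biotin and hybridised to Affymetrix arrays. The deposited values are log2 signals made by the authors with RMA, per the submitters' processing notes, which name the tool without a version. RMA corrects background, quantile normalizes probes and summarises them per probe set. Whether the 12 arrays were normalized together is not given in the sources used here, and the medians of the SUDHL-1 columns (4.83 to 5.0) lay below those of the other lines (5.24 to 5.35). All 12 value columns were used as deposited, on the log2 scale, with 0 columns left out. Arrays carry no read depth, so the precision rests on the number of arrays. Correlations between arrays over all genes were 0.974 to 0.984 among SUDHL-1 SP replicates, 0.973 to 0.984 among MP replicates and 0.965 to 0.986 between SP and MP, so replicates were no closer to each other than to the other population. SUDHL-1 correlated with the other lines at 0.855 to 0.908.

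Probe sets were named through the platform's annotation table, in which 19460 of 33297 had 1 gene symbol, 1754 had several and 12083 had none. Of the 19460, 19429 matched a gene of the RefSeq table (assembly GRCh38.p14) by Entrez identifier, and 0 symbols needed updating. Probe sets with several symbols named no gene. Where a gene had several probe sets (769 genes), the probe set with the highest mean over the 12 arrays stood for it, which left 18417 genes. Histone genes are near copies of each other, so their probe sets may share signal, and a value of 1 histone gene is uncertain where the copies are alike. No coordinates were used.

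Within SUDHL-1, SP minus MP was fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3) on the 6 arrays, with 4 residual degrees of freedom. Over the lines, limma tested 1 SP minus MP difference per line against 0, with the SUDHL-1 replicates averaged first (n = 4 lines, 3 residual degrees of freedom). The pair in this test comes from the cell line label. The third fit used all 12 arrays with cell line as a block and the interaction of population with SUDHL-1. P-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The 200 genes with the highest and the 200 with the lowest moderated statistic in SUDHL-1 were tested in the other 3 lines with limma's fry, which asks whether the genes of a set move, on balance, in 1 direction. Adjustment of its p over both sets was added after the results were seen.

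Gene lists were fixed before the data were examined, as were the tests, the naming rule and the first set of alternatives. Of 41 lists, 38 had at least 5 measured genes and were tested with limma's camera at a preset correlation of 0.01, adjusted over lists. The mitochondrially encoded genes (0 measured), snoRNA host genes (2 measured) and nuclear-retained long RNAs (3 measured) were not tested. The lists covered stem cell and pluripotency genes, ABC transporters, T-lineage and ALCL genes, cell cycle phases, histones, stress responses, metabolism, signalling targets, DNA repair and markers of other cell types. The classes of small nucleolar RNAs and other histone genes, and the comparison of DEL, Karpas299 and SUPM2 with each other, were added after the data were examined.

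Genes were named by a rule. It took genes past the adjusted threshold with groups that did not overlap, up to 12 in each direction, or, where fewer than 5 passed, the 5 of smallest p in each direction, given as values. It always took 13 named genes, of which 10 were measured, and up to 4 members of smallest p from each gene list described. LOC symbols, sex-linked marker genes and small RNA symbols were not named.

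Alternatives left out genes in the lowest 25% of mean signal, quantile normalized the columns again, centred each array on its median, averaged the probe sets of a gene, used a robust trended variance, used the replicate number as a block, asked for a 2-fold difference as well, fitted all 12 arrays with cell line as a block, took 50 genes for the signature, estimated the correlation within lists, used fry in place of camera, and left out each SUDHL-1 array and each line in turn. Array weights, a test of all 33297 probe sets, and fits without both arrays numbered 3, all alternatives for the interaction lists, and 4-line fits with each SUDHL-1 array left out, were added after the data were examined. In each line, the median differences of the histone, G2/M and G1/S lists were set against those of random lists. These had the same size and were matched on mean signal (10000 draws, genes drawn independently). The list tests were run again on other splits of the arrays. Each fit was tested on simulated arrays with 100 genes changed by 1 and 100 by 2 on the log2 scale. Limma made 3 false calls of 18417 in the SUDHL-1 design, 1 in the 4-line design and 10 in the interaction design, where 26% and 67% of the changed genes were recovered. In such simulated data a gene list shifted by 0.5 was called in both designs, and 0 of 37 other lists were. The simulated genes varied independently of each other. In the SUDHL-1 arrays the estimated correlation was 0.74 within the histone list and 0.72 within the G2/M list. The simulation therefore gives no rate of false list calls for the real arrays, and its shares of recovered genes need not hold for them. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.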

Results

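Side population (SP) cells, which keep little of the DNA dye Hoechst because membrane pumps export it, and main population (MP) cells, which retain it, were sorted by flow cytometry from 4 human cell lines of anaplastic large cell lymphoma (ALCL), a T-cell lymphoma. SUDHL-1, DEL, Karpas299 and SUPM2 are established lines that carry a fusion of NPM1 with the receptor kinase gene ALK. RNA was amplified and hybridised to Affymetrix gene arrays. SUDHL-1 was represented by 3 SP and 3 MP arrays, and each of the other lines by 1 SP and 1 MP array, 12 arrays in all. The values were log2 signals per probe set, from which 18417 named genes were tested. Array medians were 4.83 to 5.0 in SUDHL-1 and 5.24 to 5.35 in the other lines, and the number of arrays limits the precision. The series text speaks of sorting in triplicate but not of separate cultures, so p-values measure only the spread between these samples, which may be technical. The title of the series concerns lymphoma stem cells, and the question put to the data was which genes and gene groups SP and MP cells express at different levels.

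The first comparison set SP against MP cells within SUDHL-1. Replication-dependent histone genes, which supply histones to newly made DNA in S phase, were higher in SP cells for 27 of 27 measured members, with a median difference of 1.29 on the log2 scale. The mean over this list was 9.16 ± 0.16 (SD, n = 3) on SP arrays and 7.94 ± 0.86 (SD, n = 3) on MP arrays. Every SP array (9.02 to 9.33) lay above every MP array (6.97 to 8.60), with an exact two-sided permutation p = 0.1, the smallest value that 3 arrays against 3 can give. Genes of the G2 and M phases, which condense chromosomes and build the spindle, were higher in SP cells for 36 of 37 members, with a median of 0.66 and list means of 9.14 ± 0.33 against 8.48 ± 0.48 (SD, n = 3 each, exact permutation p = 0.2). Genes of the G1/S transition, which prepare and start DNA replication, did not share this difference, with 14 of 29 members higher, a median of -0.0057 and a mean of 0.0018.

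Among the histone genes, H2BC21 stood at 9.02 ± 0.15 in SP and 7.76 ± 0.40 in MP cells of SUDHL-1 (SD, n = 3), a difference of 1.26. The differences of H2BC11, H3C3 and H2BC8, which encode histones H2B and H3, were 0.97, 1.53 and 1.29, with standard errors of 0.18, 0.34 and 0.29. Of the G2/M genes, HJURP, the chaperone of the centromeric histone, stood at 9.09 ± 0.25 in SP and 7.88 ± 0.54 in MP cells (SD, n = 3). CENPF, a kinetochore protein, CDCA2, a mitotic phosphatase subunit, and TOP2A, the topoisomerase that untangles chromosomes, differed by 0.92, 1.08 and 0.85. In limma's camera with a preset correlation of 0.01 between genes, the histone list (adjusted p = 2.15e-29) and the G2/M list (adjusted p = 5.04e-23) were called higher in SP cells. With an estimated correlation neither list was called (adjusted p = 0.864 for both). Adjusted over the list alone, 16 of 27 histone genes and 0 of 37 G2/M genes passed limma's test, and adjusted over all genes 0 of either list did. Both medians lay lower without MP array 3, at 0.72 for the histones and 0.35 for the G2/M genes. Camera called 6 lists in the real split of the 6 SUDHL-1 arrays and up to 12 in other splits. Small nucleolar RNAs, which like these histone transcripts lack a poly(A) tail, had a median difference of 0.22 over 175 genes in SUDHL-1. Of these, 121 were higher in SP cells (camera p = 1.25e-07 with the preset correlation and 0.131 with an estimated one).

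**Figure D1:**
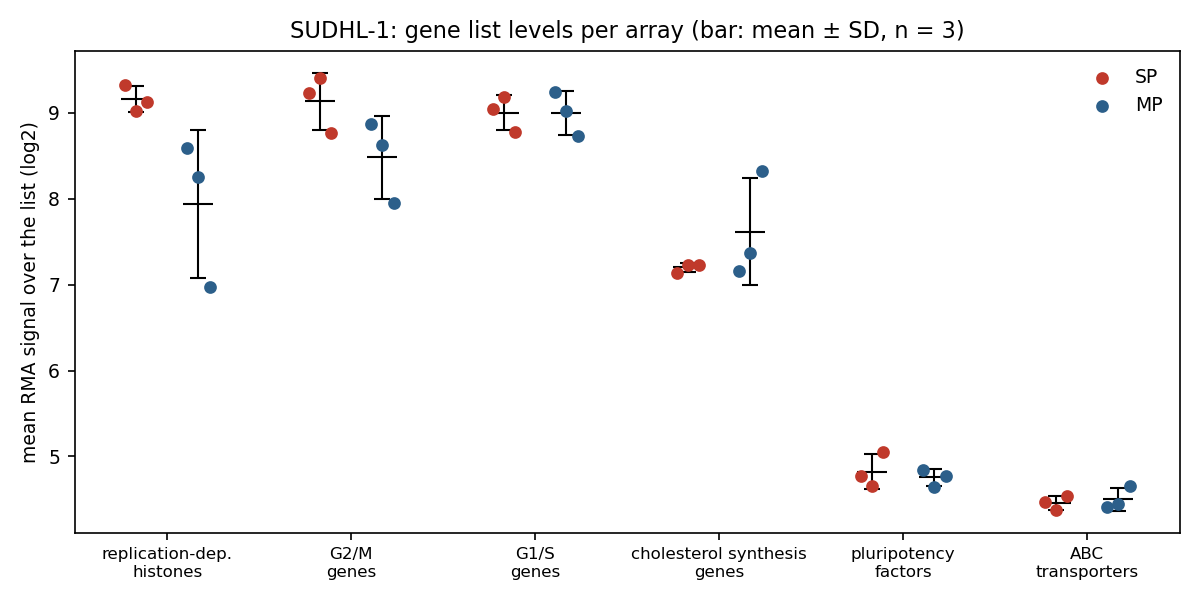
Mean RMA log2 signal over 6 gene lists (vertical axis) on each of the 3 SP and 3 MP arrays of SUDHL-1, with bars for mean ± SD (n = 3). The histone list lay at 9.02 to 9.33 on SP arrays and 6.97 to 8.60 on MP arrays, and the single high cholesterol synthesis value, 8.32, belonged to MP array 3.

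Genes of cholesterol synthesis were lower in SP cells of SUDHL-1 for 14 of 16 members, with a median difference of -0.37 (camera adjusted p = 0.00168, and 0.864 with an estimated correlation). HMGCS1, which makes the precursor of mevalonate, stood at 8.24 ± 0.59 in SP and 9.53 ± 1.49 in MP cells (SD, n = 3), and the differences of STARD4, a sterol carrier, NSDHL and FDPS were -0.84, -0.66 and -0.34. This list rested on MP array 3, whose list mean was 8.32 against 7.14 to 7.36 on the other 5 arrays, and without that array the median was -0.02 (adjusted p = 0.771, within a range of 4.33e-07 to 0.983 over the alternatives). Chaperones of the endoplasmic reticulum were lower for 14 of 15 members, with a median of -0.17 (adjusted p = 0.0170, and 0.864 with an estimated correlation). PDIA6, CANX, PDIA4 and DNAJC3, which fold secreted proteins or regulate their load, differed by -0.35, -0.31, -0.27 and -0.20. Without MP array 3 the chaperone median was -0.05 (adjusted p = 0.656, within a range of 0.000320 to 0.921), and without SP array 2 it was -0.17 (adjusted p = 0.0514). After quantile normalization the chaperone call was lost (median -0.12, adjusted p = 0.0646). Genes typical of ALK-positive ALCL were lower for 10 of 14 members, with a median of -0.14 (adjusted p = 0.0267, and 0.864 with an estimated correlation). BCL6, a transcriptional repressor, stood at 8.13 ± 0.09 in SP and 8.77 ± 0.45 in MP cells (SD, n = 3), while TNFRSF8, the CD30 antigen of this lymphoma, PTPN12 and TMOD1 differed by -0.33, -0.58 and -0.61. TMOD1 stood at -0.02 without MP array 3 and PTPN12 at -0.23 without SP array 3, and without MP array 3 HMGCS1 stood at -0.44, STARD4 at -0.29, CANX at -0.14, PDIA4 at -0.12 and DNAJC3 at -0.06. The ALCL call was lost without SP array 2 (median -0.10), SP array 3 (-0.13), MP array 1 (-0.17) or MP array 3 (-0.03). It was also lost with dim genes left out (adjusted p = 0.0611), after quantile normalization (0.0984) and with probe sets averaged (0.0518), and 4 of 14 alternatives kept it. Without both arrays numbered 3 the chaperone, cholesterol and ALCL lists were not called (adjusted p = 0.881, 0.882 and 0.853).

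Haematopoietic stem and progenitor genes were slightly higher in SP cells of SUDHL-1 for 15 of 16 members, with a median of 0.13 (camera adjusted p = 0.0267, and 0.864 with an estimated correlation). The transcription factors HHEX, MECOM and MEIS1 differed by 0.44, 0.40 and 0.31, and CD34, a surface marker of blood progenitors, by 0.29, with standard errors of 0.17, 0.20, 0.27 and 0.28. CD34 stood at -0.0149 without SP array 3, and without both arrays numbered 3 CD34 stood at -0.13 and MEIS1 at -0.0561. Markers of unrelated cell types lay on the same side, with 8 of 9 erythroid and platelet markers (median 0.13) and 13 of 16 stromal and epithelial markers (median 0.09) higher, neither list being called (adjusted p = 0.203 for each). The stem and progenitor call was lost without SP array 3 (median 0.04), MP array 1 (0.11) or MP array 3 (0.09), and without both arrays numbered 3 the median was -0.0061 (adjusted p = 0.910). It was also lost with dim genes left out (adjusted p = 0.145) and with probe sets averaged (adjusted p = 0.0518). Pluripotency factors (median 0.04, 8 of 13 higher) and ABC transporters (median -0.0052, 6 of 13 higher), the pump family that exports Hoechst dye, were not called, each with adjusted p = 0.788. DPPA4 and KLF4 differed by 0.33 and 0.38 and ZFP42 and UTF1 by -0.21 and 0.22, while the transporter genes ABCC4, ABCC1, ABCC5 and ABCG2 differed by -0.39, 0.48, -0.46 and 0.24. With 1 array left out these ran from -0.55 to -0.23, 0.25 to 0.83, -0.65 to -0.12 and 0.09 to 0.42, and 33 of the 57 genes named in SUDHL-1 moved by over 1.5 times when some array was left out. ATF4 targets, which are induced under amino acid shortage, had a median of 0.00076 (10 of 20 higher, adjusted p = 0.858, but called without MP array 3 with a median of 0.13 and an adjusted p of 0.0194), with PSAT1 and TRIB3 at 0.46 and 0.31 and SLC7A5 and VLDLR at -0.42 and -0.18. DNA repair genes had a median of -0.08 (6 of 19 higher, adjusted p = 0.793), with differences of 0.50 for LIG1, 0.47 for FANCI, -0.43 for LIG4 and -0.22 for XPA. Within the G1/S list, E2F8, UNG, EXO1 and GINS2 differed by 0.48, -0.49, 0.44 and -0.32 (camera adjusted p = 0.914), and without SP array 3 the list was called higher (median 0.13, adjusted p = 0.0411).

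The remaining 27 gene lists had median differences of -0.09 to 0.13 in SUDHL-1, and camera called none of them (adjusted p = 0.0922 to 0.893). Markers of other cell types had medians of -0.03 for B cells, 0.02 for myeloid cells, -0.05 for natural killer cells, 0.13 for erythroid cells and platelets and 0.09 for stromal and epithelial cells. Early thymic genes and T-cell receptor signalling genes had medians of 0.02 and 0.01. Among stress programmes, the medians were 0.13 for immediate early genes, -0.02 for heat shock genes, -0.05 for hypoxia genes, 0.11 for p53 targets, -0.09 for interferon-stimulated genes, 0.04 for NF-kB targets and -0.07 for NRF2 and glutathione genes. Among metabolic and ribosomal lists they were 0.0045 for glycolysis enzymes, -0.03 for nuclear respiratory chain genes, -0.0075 for ribosomal protein genes, -0.06 for ribosome biogenesis genes and 0.01 for aldehyde dehydrogenases. Targets of STAT3, WNT, NOTCH, Hedgehog and TGF-beta had medians of 0.05, 0.02, 0.08, -0.07 and -0.07. Quiescence genes, BCL2 family genes and chromatin modifiers had medians of -0.0011, -0.0019 and 0.08. The mean had the opposite sign to the median for heat shock genes (0.0086), NF-kB targets (-0.02), ribosomal protein genes (0.0080), myeloid markers (-0.07), NOTCH targets (-0.0055), TGF-beta targets (0.08), glycolysis enzymes (-0.06) and quiescence genes (0.02).

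For single genes in SUDHL-1, limma called 0 of 18417 at an adjusted p under 0.05, and 577 had an unadjusted p under 0.05 (306 higher and 271 lower in SP cells), against 921 that chance alone would give. The robust trended fit also gave 577 at that unadjusted threshold and 0 after adjustment. The genes with the smallest p were TMEM185A, a membrane protein gene at 6.69 ± 0.36 in SP and 5.16 ± 0.24 in MP cells (SD, n = 3), FAM210A, a mitochondrial protein gene at 7.80 ± 0.10 and 6.92 ± 0.13, the histones H2BC21 and H2BC11, and LYZL2, a lysozyme-like gene at 3.41 ± 0.11 and 2.42 ± 0.32. On the lower side were ZNF678, a zinc finger gene at 4.16 ± 0.35 in SP and 5.60 ± 0.14 in MP cells, FIG4, a lipid phosphatase gene at 4.85 ± 0.57 and 6.41 ± 0.18, and NIPAL2, ASAP2 and SCG5 with differences of -1.08, -1.26 and -1.67. Each of these 10 had an adjusted p of 1.00 in limma. The 3 SP values lay wholly above or wholly below the 3 MP values for 1318 genes, 7.2% of those tested, where chance gives 10%. In simulated data of the same size, limma recovered 41% of genes changed by 1 on the log2 scale and 77% of those changed by 2. The simulated genes varied independently, unlike the real ones, so these shares need not hold for the real arrays.

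Over all 4 lines, where each line gave 1 SP minus MP difference, the histone and G2/M lists had medians above 0 in each line. The histone list had medians of 1.29 in SUDHL-1, 0.87 in DEL, 0.72 in Karpas299 and 0.33 in SUPM2, with a mean of 0.80 ± 0.40 (SD, n = 4 lines, exact two-sided sign-flip permutation p = 0.125, the smallest that 4 lines can give). The linker histone gene H1-3 was higher by 1.67 ± 0.21 (SD, n = 4 lines) and had the smallest p of all genes (limma adjusted p = 0.149). Without MP array 3 of SUDHL-1 its average was 1.47 ± 0.38 (limma adjusted p = 0.960), as the SUDHL-1 difference went from 1.78 to 0.99. The histone genes H2BC10, H4C9, H2BC7, H2BC9 and H4C2 were higher by 1.54 ± 0.46, 1.36 ± 0.49, 1.21 ± 0.39, 1.13 ± 0.45 and 1.08 ± 0.25, each in 4 of 4 lines, and without that array by 1.40, 1.17, 1.06, 0.99 and 0.95. Members higher in SP cells numbered 27 of 27 in SUDHL-1, 24 in DEL, 25 in Karpas299 and 18 in SUPM2, where H2BC21, H2BC11, H3C3 and H2BC8 stood at -1.28, -0.33, -0.35 and -0.32. G2/M genes had medians of 0.66 in SUDHL-1, 0.22 in DEL, 0.43 in Karpas299 and 0.99 in SUPM2, with 36, 25, 30 and 34 of 37 members higher, and the line average was positive for 37 of 37. CDCA8 and PLK1, parts of the mitotic kinase machinery, CDK1, the kinase that starts mitosis, and KIF11, a spindle motor, were higher by 1.08 ± 0.63, 0.89 ± 0.40, 1.01 ± 0.49 and 0.52 ± 0.13 (SD, n = 4 lines).

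Camera with the preset correlation called both lists higher over the 4 lines (adjusted p = 2.19e-21 for each), and neither was called with an estimated correlation (adjusted p = 0.455 for the histones and 0.641 for the G2/M genes). Adjusted over the list alone, 15 of 27 histone genes and 13 of 37 G2/M genes passed limma's test, and adjusted over all genes 0 did. Small nucleolar RNAs had medians of 0.22 in SUDHL-1, -0.07 in DEL, 0.12 in Karpas299 and -0.03 in SUPM2. The G1/S list did not move in 1 direction, with medians of -0.50 in DEL, -0.50 in Karpas299, -0.0057 in SUDHL-1 and 0.34 in SUPM2. Members of this list were higher in SP cells for 0 of 29 genes in DEL, 2 in Karpas299, 14 in SUDHL-1 and 21 in SUPM2. CCNE1 and CCNE2, the E-type cyclins, and MCM3 and MCM4, parts of the replicative helicase, averaged -0.55 ± 0.32, -0.45 ± 0.27, -0.27 ± 0.09 and -0.40 ± 0.39 (SD, n = 4 lines). The G1/S list was called lower (median of the averages -0.13, camera adjusted p = 0.00239, and 0.663 with an estimated correlation). Without DEL its median was 0.09 (adjusted p = 0.645) and without Karpas299 -0.05 (adjusted p = 0.212), within a range of 2.81e-13 to 0.714 over the alternatives.

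**Figure D2:**
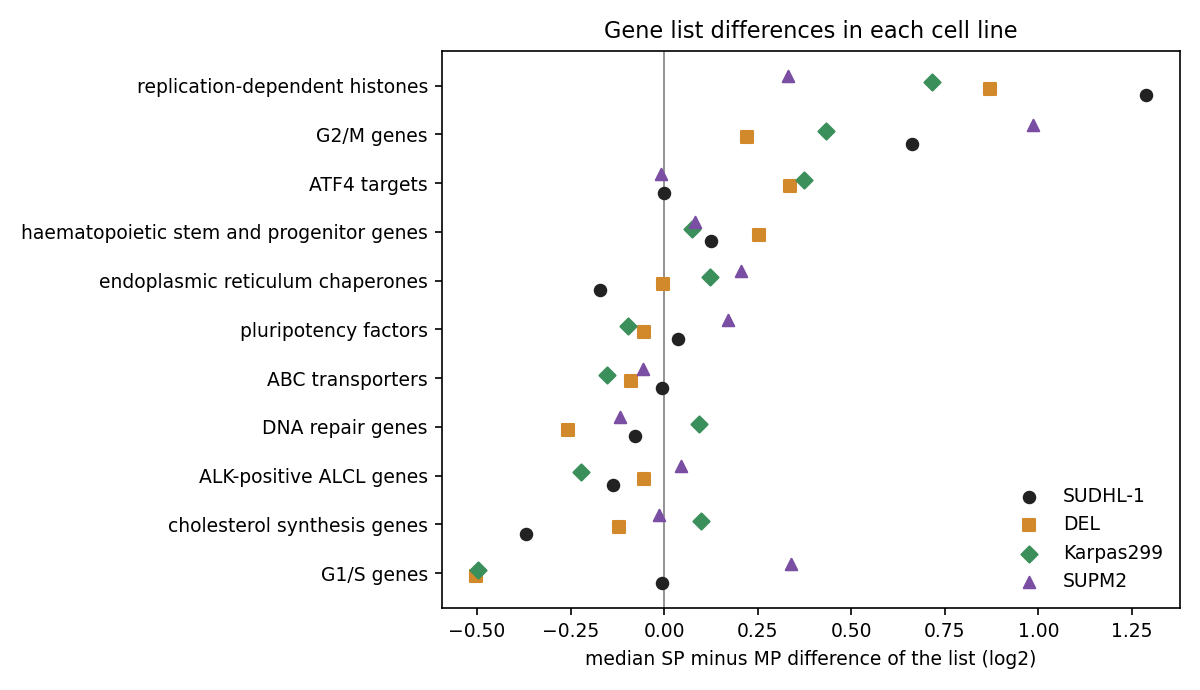
Median SP minus MP difference on the log2 scale (horizontal axis) of 11 gene lists in each of the 4 cell lines, with 1 point per line. The histone and G2/M medians lay above 0 in every line, from 0.33 to 1.29 and from 0.22 to 0.99, while the G1/S medians ran from -0.50 to 0.34.

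DNA repair genes were lower on the average of the 4 lines for 15 of 19 members, with a median of -0.14 (camera adjusted p = 0.0246, and 0.641 with an estimated correlation). The line medians were -0.08 in SUDHL-1, -0.26 in DEL, 0.09 in Karpas299 and -0.12 in SUPM2. In Karpas299, 10 of 19 members were higher in SP cells. CHEK2, a checkpoint kinase, BRCA1 and ATR averaged -0.49 ± 0.62, -0.21 ± 0.18 and -0.24 ± 0.29, and XRCC4, which joins DNA ends, 0.32 ± 0.43 (SD, n = 4 lines). ATF4 targets were higher for 15 of 20 members, with a median of 0.13 (adjusted p = 0.0169, and 0.641 with an estimated correlation) and line medians of 0.34 in DEL, 0.37 in Karpas299, 0.00076 in SUDHL-1 and -0.0075 in SUPM2. PSAT1, an enzyme of serine synthesis, averaged 0.63 ± 0.26, and DDIT4, CHAC1 and SESN2, which respond to stress, averaged 0.46 ± 0.41, 0.44 ± 0.46 and 0.43 ± 0.45 (SD, n = 4 lines). Haematopoietic stem and progenitor genes were higher for 14 of 16 members, with a median of 0.14 (adjusted p = 0.0184, and 0.641 with an estimated correlation). Stromal and epithelial markers (11 of 16 higher, median 0.12) and erythroid and platelet markers (7 of 9, median 0.08) lay on the same side without being called (adjusted p = 0.261 and 0.345). The progenitor factors MEIS1, TAL1, KIT and ANGPT1 averaged 0.52 ± 0.53, 0.31 ± 0.39, 0.28 ± 0.22 and 0.19 ± 0.12. KIT and ANGPT1 lay at 2.31 to 3.64 and 2.73 to 3.65, in the lowest 25% of signals on every array. The DNA repair call was lost without DEL (median -0.08) or SUPM2 (-0.11), with dim genes left out (adjusted p = 0.0583), after quantile normalization (0.0525) and without both SUDHL-1 arrays numbered 3 (0.198), and it was also lost without SP array 3 (-0.11) or MP array 1 (-0.13) of SUDHL-1. Single lines or arrays also decided the ATF4 call, lost without DEL (0.01), Karpas299 (0.11), SP array 3 (0.13) or MP array 1 (0.09), and the stem and progenitor call, lost without SUDHL-1 (0.11), DEL (0.12) or SP array 3 (0.09) and without both arrays numbered 3 (adjusted p = 0.147).

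Lists called within SUDHL-1 did not all recur over the 4 lines. Cholesterol synthesis genes had line medians of -0.37 in SUDHL-1, -0.12 in DEL, 0.10 in Karpas299 and -0.01 in SUPM2 (camera adjusted p = 0.261 over the 4 lines, and 0.0447 without Karpas299, where the median was -0.17). DHCR7, CYP51A1 and FDPS, enzymes of this pathway, averaged -0.51 ± 0.51, -0.33 ± 0.26 and -0.22 ± 0.08, and MVK 0.27 ± 0.36 (SD, n = 4 lines). The CYP51A1 value rested on the choice of probe set, and was 0.0052 with its probe sets averaged. Without MP array 3 the SUDHL-1 difference of DHCR7 went from -0.80 to -0.02 and its average to -0.31, and those of CYP51A1 to -0.0097 and -0.24. Endoplasmic reticulum chaperones had medians of -0.17 in SUDHL-1, -0.0044 in DEL, 0.12 in Karpas299 and 0.20 in SUPM2 (adjusted p = 0.550), with DNAJB9, XBP1, HERPUD1 and SEL1L at averages of 0.25, 0.22, 0.15 and 0.15. ALK-positive ALCL genes had a median of -0.15 (adjusted p = 0.0708, and 0.0399 without MP array 2), with TNFRSF8 and MUC1 at -0.47 ± 0.68 and -0.65 ± 1.04 and CEBPB and BCL2A1 at 0.38 ± 0.54 and 0.42 ± 0.68. Pluripotency factors (median 0.10, adjusted p = 0.347) and ABC transporters (median -0.09, adjusted p = 0.261) were not called. ZFP42, DPPA4 and UTF1 averaged 0.57 ± 0.75, 0.15 ± 0.17 and 0.20 ± 0.16, and the transporter genes ABCC5, ABCC3 and ABCG1 -0.38 ± 0.34, -0.21 ± 0.25 and 0.18 ± 0.16. ZFP42 stood at 8.03 in SP and 6.50 in MP cells of SUPM2, and at only 2.73 to 4.02 on the arrays of the other lines. DPPA4 lay at 3.35 to 4.13 on all arrays. The remaining 27 lists had medians of -0.11 (interferon-stimulated genes, adjusted p = 0.0708) to 0.21 (T-cell receptor signalling genes, adjusted p = 0.264), and none was called.

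For single genes over the 4 lines, limma called 0 of 18417 at an adjusted p under 0.05, and 904 had an unadjusted p under 0.05 (468 higher and 436 lower), against 921 by chance. The robust trended fit gave 901 at that unadjusted threshold and 0 after adjustment. On the lower side the smallest p belonged to GTF2H5, a subunit of the repair and transcription factor TFIIH, with an average of -0.76 ± 0.18 (SD, n = 4 lines). CNTD1, RBM14, an RNA-binding protein gene, TNC, which encodes the matrix protein tenascin C, and IGIP averaged -0.83 ± 0.25, -1.02 ± 0.38, -0.65 ± 0.12 and -0.74 ± 0.25, each lower in 4 of 4 lines. The SUDHL-1 differences of CNTD1 and TNC rested on MP array 3, without which they went from -0.45 to -0.03 and from -0.81 to -0.10. That of RBM14 went from -0.58 to -0.25 without SP array 3, and that of GTF2H5 from -0.92 to -0.33 without SP array 1. The difference had the same sign in all 4 lines for 2532 genes, 13.7% of those tested, where chance gives 12.5%. In simulated data of the same size, whose genes varied independently, 54% of genes changed by 1 on the log2 scale were recovered. Of those changed by 2, 87% were recovered, and neither share need hold for the real arrays.

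The genes named in advance as stem cell, dye transporter and lymphoma markers gave no call in any comparison (limma adjusted p of 0.918 or more over the 4 lines). SOX2, a pluripotency factor, averaged -0.57 ± 0.41 (SD, n = 4 lines, SE 0.17), with -0.07 in SUDHL-1, -1.06 in DEL, -0.56 in Karpas299 and -0.60 in SUPM2. The SUDHL-1 value turned its sign in 3 of 6 fits with 1 array left out, from -0.42 to 0.26. ABCG2, the pump most often tied to the SP phenotype, stood at 1.21 in DEL, 0.30 in SUPM2, 0.24 in SUDHL-1 and -0.37 in Karpas299, an average of 0.34 ± 0.65. The drug transporter genes ABCB1 and ABCC1 averaged 0.15 ± 0.12 and 0.15 ± 0.63. MYC averaged 0.27 ± 0.55, with 1.06 in Karpas299 and -0.17 to 0.15 in the other lines. KLF4 was 0.38 higher in SUDHL-1 and -0.07, -0.13 and -0.17 in DEL, Karpas299 and SUPM2. The progenitor markers CD34 and PROM1 averaged 0.17 ± 0.09 and 0.11 ± 0.13. PROM1 lay at 2.15 to 3.39, in the lowest 25% of signals on every array. TNFRSF8 was lower by -1.46 in Karpas299 and stood at -0.33, -0.20 and 0.10 in SUDHL-1, DEL and SUPM2. MKI67, a marker of dividing cells, was 9.62 ± 0.59 in SP and 8.64 ± 0.32 in MP cells of SUDHL-1 (SD, n = 3), while DEL, Karpas299 and SUPM2 gave -0.01, 0.16 and -0.35. POU5F1, NANOG and ALK were not analysed here, because their probe sets name several genes.

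**Figure D3:**
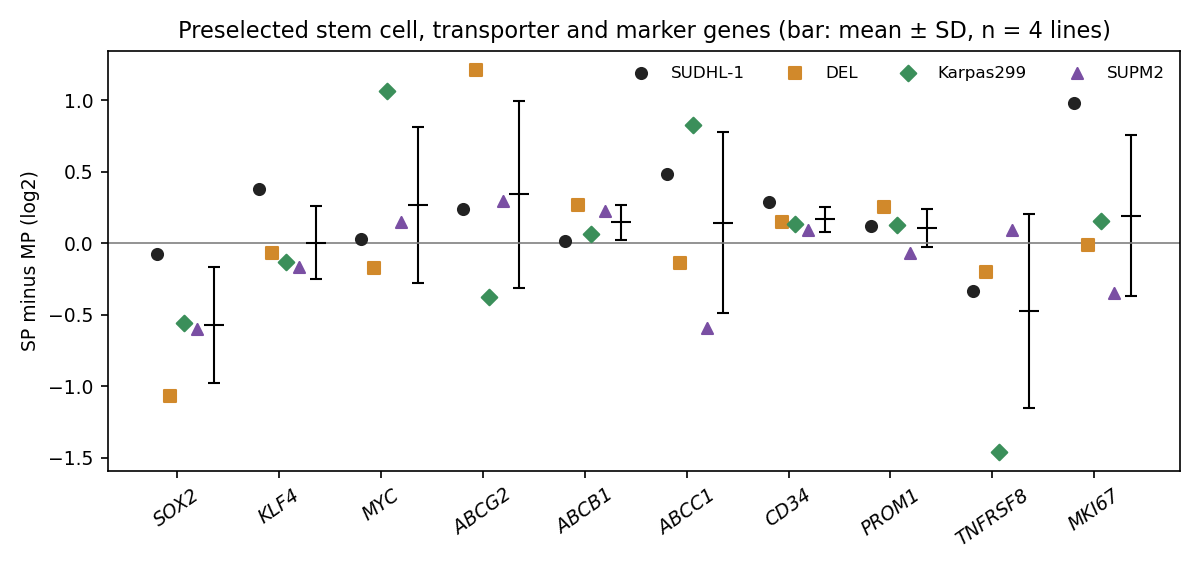
SP minus MP difference on the log2 scale (vertical axis) of 10 genes named in advance, with 1 point per cell line and bars for mean ± SD (n = 4 lines). SOX2 ran from -1.06 in DEL to -0.07 in SUDHL-1, where its sign turned in 3 of 6 fits with 1 array left out, and ABCG2 ran from -0.37 to 1.21.

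The third comparison asked whether the SP minus MP difference of SUDHL-1 was that of the other 3 lines. SLPI, which encodes a secreted protease inhibitor, was 0.45 higher in SP cells of SUDHL-1 and stood at -1.34, -0.71 and -1.36 in DEL, Karpas299 and SUPM2. Its signal was low on the SUDHL-1 arrays, at 3.90 to 4.68 where the array medians were 4.83 to 5.0. In the other lines it was 6.20 to 11.20. PRKCQ, the protein kinase C of T-cell receptor signalling, TINF2, a telomere protein gene, and the pseudogene TOB2P1 had differences that were larger in SUDHL-1 by 1.78, 1.21 and 1.30, with standard errors of 0.32, 0.21 and 0.23, and TMEM185A by 1.47. RHOH, a GTPase of blood cells, and FCER1G, the shared signalling chain of Fc receptors, went the other way, with -0.51 and -0.39 in SUDHL-1 against 0.77 to 1.25 and 0.62 to 0.94 in the other lines. ZNF678, SCG5 and the pseudogene ZNF847P had interaction values of -1.74, -2.26 and -1.18. ZNF847P lay at 1.77 to 2.85, in the lowest 25% of signals on every array. FCER1G, on the natural killer marker list, was the only member of that list to pass adjusted over the list alone (limma adjusted p = 0.00165). It was named here for its small p among all genes, and adjusted over all genes none passed (smallest limma adjusted p = 0.738). Camera did not call the natural killer list (adjusted p = 0.133).

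Among the gene lists, camera with the preset correlation called 4 of 38 as different between SUDHL-1 and the other lines, and with an estimated correlation it called 0 (smallest adjusted p = 0.979). The SP minus MP difference of SUDHL-1 was larger for the histone list (median 0.53, 22 of 27 members, adjusted p = 0.00197, and 0.979 with an estimated correlation) and the G1/S list (median 0.15, 20 of 29 members, adjusted p = 0.0413, and 0.979). It was smaller for the chaperones of the endoplasmic reticulum (median -0.24, 15 of 15 members, adjusted p = 0.0202, and 0.979 with an estimated correlation) and for cholesterol synthesis (median -0.52, 15 of 16 members, adjusted p = 0.0202, and 0.979). These calls rested on MP array 3 of SUDHL-1, and without it 0 lists were called, with medians of 0.028 for the histones (adjusted p = 0.858), -0.0311 for G1/S (0.475), -0.15 for the chaperones (0.463) and -0.0914 for cholesterol synthesis (0.773). The histone call was also lost without SUPM2 (median 0.24), the chaperone call without Karpas299 (-0.29) or SUPM2 (-0.21), and the cholesterol call without SP array 1 (-0.54) or Karpas299 (-0.42). The G1/S call was also lost without SP array 1 (0.12), SP array 2 (0.0064), MP array 2 (0.16), DEL (-0.15) or Karpas299 (0.01) and with arrays centred (0.18, adjusted p = 0.0887). For single genes limma called 0 of 18417, with 661 at an unadjusted p under 0.05 (651 in the robust trended fit) and a smallest adjusted p of 0.738. Of the genes named in advance, MKI67 and SOX2 had interaction values of 1.05 and 0.67, with standard errors of 0.40 and 0.46, and TNFRSF8, ABCG2 and MYC 0.19, -0.14 and -0.32. The SUDHL-1 arrays stood apart from the others on the first principal component, which held 60.3% of the variance, and cell line and array set cannot be told apart.

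The last comparison carried the SUDHL-1 ranking to the other lines. The 200 genes with the highest SP against MP statistic in SUDHL-1 had a median difference of 0.13 over DEL, Karpas299 and SUPM2, and 65.5% of them were higher there (limma fry adjusted p = 0.280 over both sets, two-sided). Their medians were 0.06 in DEL, 0.16 in Karpas299 and 0.09 in SUPM2, where the medians over all genes were 0.02, -0.0059 and 0.07. The share of all genes that were higher was not computed for comparison with the 65.5%. The 200 genes with the lowest statistic had a median of -0.02, and 51.5% were lower (limma fry adjusted p = 0.786). With each array centred on its median, the upper and lower sets had medians of 0.0808 and -0.0461. Across all genes, which are not independent replicates, Pearson correlations of the SP minus MP difference between lines were -0.06 to 0.08. At least 2-fold differences numbered 139 genes in SUDHL-1, where 3 arrays were averaged in each population, and 450, 589 and 1213 in DEL, Karpas299 and SUPM2 with 1 array in each.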

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

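The tests of the histone and G2/M lists in this part, and the interaction and 4-line fits with SUDHL-1 arrays left out, were chosen after the results were seen. In the linker histone gene H1-3 the SUPM2 difference, 1.36, lay apart from those of the other 3 lines, 1.74 to 1.81, with a gap of 0.841 of the whole range. The SUDHL-1 value of 1.78 rested on MP array 3, and without it SUDHL-1 stood at 0.99, below SUPM2, so SUPM2 no longer stood apart as the lowest. In DNAJB9, a chaperone gene of the endoplasmic reticulum, the DEL difference of 0.84 lay apart from the other lines, 0 to 0.10, with a gap of 0.875 of the range. Of 69 genes and lists examined over the 4 lines, these 2 passed the limit of 0.829 for 4 values, and chance alone passes about 1 in 20.

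In the limma interaction fit the SP minus MP difference of SUDHL-1 exceeded that of the other lines by a median of 0.53 over the histone list (adjusted p = 0.00197, and 0.979 with an estimated correlation). The G1/S list exceeded it by 0.15 (adjusted p = 0.0413, and 0.979). The endoplasmic reticulum chaperones lay below it at -0.24 and the cholesterol synthesis genes at -0.52 (adjusted p = 0.0202, and 0.979, for each). Without MP array 3 of SUDHL-1 none of the 4 lists was called, with medians of 0.028, -0.0311, -0.15 and -0.0914 (adjusted p = 0.858, 0.475, 0.463 and 0.773). Outside the named genes, the unnamed probe set 7895584 was the only 1 called in SUDHL-1 when all probe sets were tested (it names no gene and was not identified as a gene or a control), at 6.17 ± 0.15 in SP and 2.47 ± 0.23 in MP cells (SD, n = 3), a difference of 3.69 with a limma adjusted p of 0.0108. Its difference was 2.95 in Karpas299, 0.06 in DEL and -0.32 in SUPM2.

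Histone and G2/M list medians were above 0 in all 4 lines, the lowest of the 8 being 0.22 (G2/M in DEL, 25 of 37 members higher). The sign of the average thus did not come from 1 line alone. Each median lay above at least 99.18% of random lists, but these draw genes independently and lack the correlation within the 2 lists. They also give no spread between arrays, and DEL, Karpas299 and SUPM2 had 1 array per population. Over the lines the exact sign-flip permutation p was 0.125 for each list, the smallest that 4 lines can give. Other lists reached the same p. The stem and progenitor, early thymic, T-cell receptor signalling, p53 target and NOTCH target medians were above 0 in every line. The ABC transporter medians were below 0 in every line, from -0.15 to -0.0052. One sign in all lines was thus not particular to the histone and G2/M lists. For the histones the lowest SP array of SUDHL-1 lay 0.43 above the highest MP array, which argues against 1 array setting the order, whereas for G2/M genes, whose means overlapped (-0.10), the median stayed at 0.35 to 0.83 with each array left out, but the difference in means without MP array 3, 0.39 with a standard error of 0.23 (exact p = 0.3), lay within the spread between arrays and leaves that array open. Better recovery of RNA without a poly(A) tail has no bearing on the G2/M genes, whose transcripts have a tail. Their medians above 0, the lowest being 0.22, are the pattern itself and no test of it. For the histones such recovery could contribute. Small nucleolar RNAs went both ways over the 4 lines, with medians of 0.22 in SUDHL-1, 0.12 in Karpas299, -0.07 in DEL and -0.03 in SUPM2. Their camera p over the lines was 0.470 with the preset correlation and 0.704 with an estimated one. In SUDHL-1 alone 121 of 175 were higher in SP cells (camera p = 1.25e-07 with the preset correlation and 0.131 with an estimated one). A larger S-phase share of SP cells stays open in all 4 lines. In DEL and Karpas299 the G1/S medians were -0.50 at most, while the histone medians were 0.87 and 0.72. G1/S genes prepare and start replication, so their low level does not decide on cells further into S phase. Each of these medians also came from 1 SP and 1 MP array. In SUDHL-1 and SUPM2 the lower of the G1/S medians was -0.0057. A larger share of SP cells in late S, G2 or M phase stays open as a biological explanation that was not tested, and the higher DNA content of such cells would by itself raise their dye signal and so move them toward the MP gate.

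Other splits of the 6 SUDHL-1 arrays called as many lists as the real split in 8 of 10 cases, the real one included, with 6 lists in the real split and 12 in the highest other. Turning the sign of whole lines gave as many lists in 2 of 8 cases, with 6 in the real arrangement and 7 in the highest other. The numbers of splits, 10 and 8, are too few for a share under 0.05. The histone median was 1.29 in the real SUDHL-1 split and 0.98 in the highest other, and the G2/M median 0.66 and 0.70. Over the 4 lines the medians were 0.78 and 0.69 for the histones and 0.57 and 0.50 for the G2/M genes.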

How the results depend on the processing

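The added settings here are array weights, all probe sets, the fits without both arrays numbered 3, the alternatives of the interaction lists and the 4-line fits with SUDHL-1 arrays left out. Limma called 0 named genes in SUDHL-1, over the 4 lines and in the interaction under every setting run on named genes, with 577, 904 and 661 at an unadjusted p under 0.05 in the fits reported and up to 1918 with array weights in SUDHL-1. Testing all probe sets gave 1 call in SUDHL-1, an unnamed probe set. The signature by genes past the adjusted threshold was not run, because there were none. The numbers of SUDHL-1 replicates did not pair the arrays (correlations of deviations -0.004, -0.077 and -0.132), and with the replicate number as a block 0 genes were called (608 at an unadjusted p under 0.05) and 6 lists.

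With an estimated correlation, and with fry, camera's 6 lists in SUDHL-1 and 6 over the 4 lines became 0. With 1 array left out SUDHL-1 gave 4 to 8 lists, with ATF4 targets gained without MP array 3 and G1/S genes without SP array 3. The 4 lines gave 2 to 8 lists with 1 line left out, and 3 without SP array 3, 4 without MP array 1 and 6 or 7 without another array of SUDHL-1. The 4 interaction lists became 0 with an estimated correlation, without MP array 3 and without both number 3 arrays, and were 1 without Karpas299, 2 without SP array 1 and 8 without SP array 3. The upper signature median was 0.13, 0.0546 to 0.20 with 1 array or line left out and 0.35 with 50 genes. It was 0.0808 with arrays centred and 0.0332 without both number 3 arrays. With trended variances (0.14) and without MP array 2 (0.12) its fry p was under 0.05 before adjustment over both sets and not after it (limma adjusted p = 0.0991 for each). The lower median ran from -0.0722 to 0.0413 with 1 array or line left out and was -0.14 with 50 genes and 0.0065 without both number 3 arrays, and without MP array 1 (-0.0574) its adjusted p was 0.0521 in limma, under 0.05 before adjustment. Other signs turned as well, some of them for values away from 0 (CYP51A1 -0.33, SLC7A5 -0.42, MEIS1 0.31, CD34 0.29, UTF1 0.22), and the cause was not tested. Quantile normalization gave -0.0011 for ABCB1 in SUDHL-1 and -0.0177 for KLF4 over the 4 lines, and centring -0.0079 for KLF4. Averaged probe sets gave 0.0052 for CYP51A1, array weights -0.0377 for MEIS1, and fry a G1/S median of -0.0057 with a direction opposite to camera's. Without both number 3 arrays, SUDHL-1 gave -0.0196 for ABCB1, -0.13 for CD34, -0.0561 for MEIS1, 0.0502 for SLC7A5, -0.0352 for UTF1, -0.0502 for pluripotency factors and 0.12 for DNA repair genes, and the interaction -0.26 for CD34 and -0.0194 for PROM1.

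With 1 array left out, SUDHL-1 values ran from -0.17 to 0.13 for the G1/S list, -0.42 to 0.26 for SOX2, -0.0932 to 0.0367 for ABC transporters, -0.0694 to 0.18 for MYC, -0.0873 to 0.0895 for ABCB1, -0.0149 to 0.48 for CD34, -0.0611 to 0.18 for pluripotency factors, -0.11 to 0.13 for ATF4 targets and -0.16 to 0.0732 for DNA repair genes. With 1 line or SUDHL-1 array left out, averages ran from -0.12 to 0.061 for KLF4, -0.0673 to 0.38 for MKI67, -0.0819 to 0.39 for ABCC1, -0.17 to 0.12 for cholesterol synthesis and -0.0741 to 0.0717 for the chaperones. Interaction values ran from -0.14 to 0.35 for CD34, -0.072 to 0.0907 for PROM1, -0.51 to 0.28 for ABCG2, -0.58 to 0.0384 for MYC and -0.28 to 0.50 for TNFRSF8. Arrays carry no depth, and signal over background limits the dim genes.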

Other observations

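The comparison of DEL, Karpas299 and SUPM2 with each other, its counts per gene list, and the test of array sets, were chosen after the data were examined. Among these 3 lines a limma F test with population as a term called 1382 of 18417 genes (adjusted p under 0.05), 7.5% of those tested. The 2 arrays of a line were its SP and MP cells, and neither population had a replicate. The p-values thus measure only how the SP minus MP difference varies between lines, and not the spread between cultures of a line. Of the T-cell receptor signalling list 6 of 14 genes were called, and larger shares were called in the G1/S list (19 of 29), the ATF4 targets (10 of 20), the ribosome biogenesis list (12 of 25) and the p53 targets (9 of 20). The interleukin 7 receptor gene IL7R stood at 7.96 in DEL, 5.99 in Karpas299 and 3.06 in SUPM2 (limma adjusted p = 0.00657). CD4, the co-receptor of helper T cells, was lower in DEL, at 4.80, than in Karpas299 and SUPM2, at 9.60 and 9.49 (adjusted p = 0.00688), and CD2, an adhesion molecule, was highest in SUPM2, at 9.19 against 4.40 and 4.44 (adjusted p = 0.00273). The T-cell receptor chain genes CD3D and CD247 were lower in DEL, at 5.68 and 5.05, than in Karpas299 (9.63 and 7.56) and SUPM2 (9.10 and 8.30). Karpas299 had the highest signal of the 3 for CD5 (9.02), for the adaptor gene LCP2 (9.05) and for ZAP70 (7.79), the kinase that binds the T-cell receptor. The granule gene GZMB was lower in DEL, at 9.77, than in Karpas299 (11.56) and SUPM2 (11.89). The number of called genes was 1171 to 1395 under the other settings.

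Small p-values were fewer in SUDHL-1 than chance alone would give, with 3.13% of genes under an unadjusted p of 0.05. Equally numbered arrays that share a structure are argued against as the reason, because a block for the number left the share at 3.3%. The 2 arrays numbered 3 lay at opposite ends of the first principal component of the 6 arrays (-39.5 for SP and 39.3 for MP). Without both, the share was 5.46%. Of the 9 ways to leave out 1 SP and 1 MP array, 2 reached that share, namely this pair and SP array 2 with MP array 3 (5.49%). Both ways left out MP array 3, so arrays 3 may contribute and their part stays open. All 10 splits of the 6 arrays gave at least the 0 called genes of the real split (highest other 1). So did 8 of 8 sign turns of the lines (highest other 0) and 80 of 80 splits for the interaction (highest other 1). Since a count of 0 is reached by every split, these counts of called genes tell nothing about chance. At an unadjusted p under 0.05 in limma, the real SUDHL-1 split gave 577 genes and the other splits 446 to 1495, most of them more. The real grouping thus separated fewer genes than most other groupings of the same arrays.

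The SUDHL-1 arrays stood apart from the other lines on a first component with 60.3% of the variance. Different value distributions of the array sets are argued against as the whole cause, because the component still held 55.5% after quantile normalization of the 12 columns. A separate array batch could also set SUDHL-1 apart and cannot be told apart from the cell line, because 0 blocks of consecutively deposited samples held both SUDHL-1 and another line. The biological difference between the lines stays open as well and was not tested.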
